A study of Mus musculus with 15 samples.

How the data were processed

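The series holds 15 samples of C57BL/6 mouse bone marrow-derived macrophages or of chromatin assembled from their DNA. PU.1 is the ETS-family transcription factor that sets macrophage identity. Macrophages differentiated for 7 days carried a doxycycline-inducible retroviral hairpin against PU.1 (shPU.1) or a control vector with a hairpin against Renilla luciferase. The titles of the control samples call this vector empty. Per the labels' protocols, puromycin selection at 3 µg/ml began on day 3 and doxycycline at 0.5 µg/ml was given from day 5 for 48 hours before chromatin immunoprecipitation (ChIP). Crosslinking was with 1% formaldehyde (10 min). Each group had 2 ChIP libraries. A separate pair of ChIP libraries came from nucleosomes assembled in vitro on sonicated naked macrophage DNA with recombinant histones. These nucleosomes were incubated for 2 hours with macrophage nuclear extract that had been depleted with normal IgG or with an anti-PU.1 antibody (8 µg). The remaining 9 samples, in 4 groups, are micrococcal nuclease (MNase) digests and were not analysed here.

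Reads were aligned with Bowtie 0.12.7 to mouse build mm9 and peaks were called with MACS 1.4, per the submitters' processing notes. Parameters of these steps are not given in the sources used here. The 5 deposited lists are BED files with a peak score in the fifth column. In vivo peaks were called for each library against an input, per the deposited files' names, and replicates were not pooled. The in vitro list was called on the IgG-depleted library with the PU.1-depleted library as control. Its peaks therefore mark DNA recovered by the PU.1 antibody more often with an extract containing PU.1 than with a depleted one. MACS of this generation by convention writes the score as 10 times the negative log10 of the peak p-value, and the lowest score in any of the deposited lists was 50. The score grows with sequencing depth, so it was used only to rank or filter peaks within a list. The lists hold no read counts: the depth of each library is unknown, and no value could be corrected for it. A library with fewer reads, or with a weaker immunoprecipitation, gives fewer peaks at the same threshold. The last peak on chromosome 1 ended at 197137158, and all coordinates below are in mm9, counted from 1.

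Peaks of the 4 in vivo lists were merged into regions where they shared at least 1 bp. A control region held a peak of both control libraries. It was called kept if both shPU.1 libraries had a peak there, lost if neither did, and partial if 1 did. A gained region held a peak of both shPU.1 libraries and of no control library. The rank of a region was the mean of its score percentiles within the 2 control lists, with 100 as the highest. Where a region held several peaks of a list, the highest percentile was taken. Regions were merged over all 4 lists, so shPU.1 peaks can join control peaks and raise the rank of kept or partial regions. This was not corrected. Overlap with the in vitro list needed at least 1 bp. Chance overlap was taken from 100 placements of the in vitro peaks at random positions on the same chromosome, up to the last peak in any list. Odds ratios of being kept rather than lost were combined over 10 strata of rank by the Mantel-Haenszel method. Their 95% intervals came from 1000 draws of 10 Mb bins of the genome. Shares carry exact (Clopper-Pearson) 95% intervals. Both kinds of interval cover counting of regions within these libraries only, not the variation between cultures, because regions are not replicates.

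With 2 libraries against 2, an exact two-sided permutation test cannot give a p below 0.33, so group differences are set beside the difference between replicates. The labels number the replicates but do not say whether they came from separate mice or cultures, and the spread between them may be technical. Named regions were the 5 highest by mean rank in each class, or by score in the in vitro list, a rule fixed before the data were examined, as were the tests of the comparisons between groups and with the in vitro list and most alternatives. Odds ratios between single lists and the tests of explanations were chosen later. The 3 results planned on sequence or genes (promoters, a PU.1 motif, gene lists) needed mm9 sequence or annotation, which was not used here. The gene table used for names is on GRCm38, a different build, so regions are named by their mm9 positions without gene names.

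The alternatives tried were a minimum score of 100, peaks trimmed to their central 200 bp, lists limited to the length of the shortest, each library left out in turn, the replicate number as a block, in vitro peaks shifted by 50 kb, a larger overlap and other strata. The code was tested on simulated shPU.1 lists made from the real control lists, with 21975 control regions. It recovered an odds ratio of 2.97 (95% interval 2.75 to 3.19) where 3 was put in and of 1.02 (0.948 to 1.10) where 1 was put in. Both simulated shPU.1 lists were identical, so partial regions and differences between the shPU.1 replicates were not simulated. Simulated kept peaks took the exact bounds of their control regions, and keeping was drawn from rank and in vitro overlap. Differences in peak width, depth and calling between lists were therefore not simulated either. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.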

Results

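Binding of PU.1 was mapped by ChIP followed by sequencing in mouse macrophages carrying the control vector (n = 2 libraries) or the PU.1 hairpin (n = 2 libraries). It was also mapped on nucleosomes assembled in vitro (1 list from a pair of libraries). The control libraries had 30026 and 36759 peaks and the shPU.1 libraries 15122 and 27733 peaks. The in vitro list had 57512 peaks. Median peak width followed the replicate number more than the group: it was 435 bp and 448 bp in control and shPU.1 replicate 1, and 892 bp and 1076 bp in control and shPU.1 replicate 2. Whether peaks of both replicates were called with the same settings is not given in the sources used here. Sequencing depth is unknown for every list.

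The first comparison asked how many PU.1 sites could be detected after the hairpin against PU.1 was induced. Peaks numbered 33392.5 ± 4760.9 (SD, n = 2) in control libraries and 21427.5 ± 8917.3 (SD, n = 2) in shPU.1 libraries, a log2 ratio of -0.64 (-0.27 without shPU.1 replicate 1 and -1.14 without shPU.1 replicate 2). The shPU.1 library had fewer peaks than the control library of the same number in both cases, with 0.504 times as many in replicate 1 and 0.754 times as many in replicate 2. The mean under the hairpin differed by -11965 peaks, with an exact two-sided permutation p of 0.33, the smallest that 2 against 2 libraries can give. The difference between the 2 shPU.1 libraries was of similar size to the difference between the groups. The lists do not measure PU.1 protein or transcript, so the strength of the knockdown could not be read from them.

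**Figure D1:**
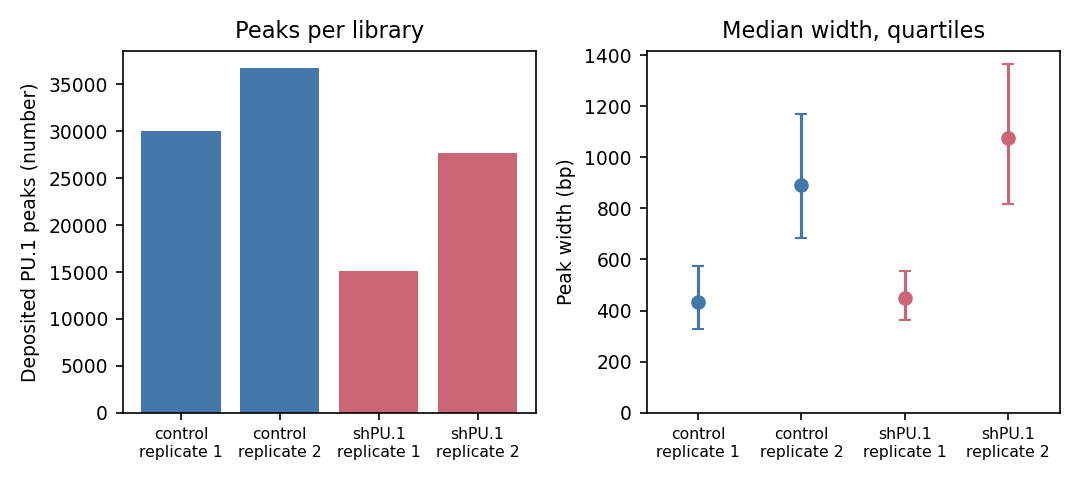
Deposited PU.1 peaks per library (left, bars) and peak width in bp (right, points are medians and bars run from the lower to the upper quartile) for control and shPU.1 libraries. The shPU.1 libraries have 15122 and 27733 peaks against 30026 and 36759 in controls, and median widths separate replicate 1 (435 and 448 bp) from replicate 2 (892 and 1076 bp).

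The second comparison asked which control sites were still bound. The 4 lists merged into 53107 regions, of which 21680 were control regions. Of these, 8666 regions (40.0%, exact 95% interval 39.3 to 40.6) were kept, 6301 (29.1%, 28.5 to 29.7) were lost from both shPU.1 libraries, and 6713 (31.0%, 30.3 to 31.6) were partial. The partial regions lay mostly on 1 side: 5964 had a peak only in shPU.1 replicate 2, and 749 only in shPU.1 replicate 1. The list of shPU.1 replicate 2 had the widest peaks, and also more peaks than that of shPU.1 replicate 1 (27733 against 15122). The kept, lost and partial shares rest on overlaps of at least 1 bp, so any difference in how the replicates' peaks were called enters them. Taken singly, shPU.1 replicate 1 had a peak in 43.4% of control regions and replicate 2 in 67.5%. With 1 control library left out, regions rested on the remaining one: the kept share was 26.9% without control replicate 1 and 30.9% without control replicate 2, and the lost share 43.7% and 42.8%. The lost share was 56.9% without shPU.1 replicate 2. With all lists limited to the same number of top peaks, 58.7% were kept and 19.2% lost. Between the controls, 77.5% of the regions of replicate 1 were found in replicate 2, and 60.2% of those of replicate 2 in replicate 1. For the regions of control replicate 1, 34.7% were found in shPU.1 replicate 1 and 55.1% in shPU.1 replicate 2. For those of control replicate 2, the shares were 30.2% and 53.2%. Each of these 4 shares was below both shares between the controls. Such shares depend on the length of the second list. With 14644 regions against 27969 and 36010 in the controls, those for shPU.1 replicate 1 were bound to be lower. The list of shPU.1 replicate 2 had 27529 regions, also fewer than control replicate 2. Its length was close to that of control replicate 1. Between second lists of this like length, regions of control replicate 2 were found in 53.2% (shPU.1 replicate 2) and 60.2% (control replicate 1). In reverse, 66.3% and 74.2% of the regions of shPU.1 replicate 1 were found in control replicates 1 and 2. For shPU.1 replicate 2 these were 56.0% and 69.5%. Between the shPU.1 libraries, 69.1% of replicate 1 regions were found in replicate 2, and 36.8% of replicate 2 regions in replicate 1.

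Regions gained under the hairpin were few. Only 271 regions had a peak in both shPU.1 libraries and in no control library, against the 6301 lost ones, a log2 ratio of lost to gained of 4.54. The ratio depends on list length and on the weakest library. It was 0.92 with all lists limited to the same number of top peaks (1985 lost and 1048 gained regions), and -0.11 without shPU.1 replicate 1. It was 1.82 without shPU.1 replicate 2, 5.27 without control replicate 1 and 3.2 without control replicate 2. Splitting the libraries by replicate number gave a log2 ratio of the same size, 3468 regions in replicate 2 libraries only against 153 in replicate 1 libraries only (-4.50). The total in either direction was 6572 regions for the real split, 3621 for the split by replicate number and 1058 for the crossed split. Pairwise Jaccard similarity was 0.513 for the control pair and 0.316 for the shPU.1 pair. Its mean was 0.414 within groups and 0.346 between groups. The difference of 0.068 was the highest of the 3 splits (the others gave -0.0085 and -0.060), which is an exact permutation p of 0.33. It became -0.036 or -0.019 without control replicate 1 or control replicate 2, and 0.104 or 0.229 without shPU.1 replicate 1 or shPU.1 replicate 2.

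Control regions with higher ranks were kept more often. In the highest decile of rank in the control lists, 86.1% of regions were kept and 1.71% lost, while in the lowest decile 8.12% were kept and 64.1% lost. A kept region outranked a lost one with a probability (area under the ROC curve) of 0.767 in the list of control replicate 1 and 0.870 in that of control replicate 2, with a mean of 0.819 (95% interval 0.812 to 0.825). The mean was 0.728 with equal list lengths. Regions seen in a single list also ranked low there, with median percentiles of 22.9 and 22.9 in the controls and 27.0 and 20.4 under the hairpin. Weak peaks thus went unmatched in every library. No baseline between the controls was computed, so the link of rank with keeping cannot be ascribed to the hairpin. The control peaks of kept regions spanned a median of 1114.5 bp, against 973 bp in lost ones.

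The 5 kept regions with the highest mean rank over all 4 in vivo lists began with chromosome 11, 20011686 to 20014386. The next was at chromosome 4, 140122339 to 140123790. The other 3 were on chromosome 2, at 167749858 to 167752800, 156888388 to 156890654 and 127833398 to 127835668. The region on chromosome 11 scored 2827.3 and 3100 in the control lists and 1048.8 and 3156.4 in the shPU.1 lists. For 3 of the 5 the score in the list of control replicate 2 was 3100, a tie at the upper end of the scale, so their order does not measure strength of binding. All but the chromosome 4 region also held an in vitro peak. The highest-ranked lost region lay at chromosome 11, 116180077 to 116180959, with scores of 568.3 and 902.3 in the control lists. It was followed by chromosome 13, 63065820 to 63066601; chromosome 2, 26458980 to 26459790; chromosome 10, 62705923 to 62707502; and chromosome 8, 87184745 to 87189613. The regions on chromosomes 2 and 10 held an in vitro peak and the other lost ones named did not. The highest-ranked gained region lay at chromosome 5, 105355892 to 105357863, with scores of 182.0 and 662.8 in the shPU.1 lists. The next were chromosome X, 120115354 to 120117450; chromosome 9, 13422393 to 13423736; chromosome 15, 68435856 to 68436734; and chromosome 19, 16185049 to 16185824. All 5 of these gained regions held an in vitro peak.

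The third comparison asked how far PU.1 sites on chromatin assembled in vitro coincide with those in cells. Of the 21680 control regions, 5987 (27.6%, exact 95% interval 27.0 to 28.2) held an in vitro peak. Placement at random gave 5.11% (range 4.77 to 5.51 over 100 placements), so the observed overlap was 5.40 times higher. It was 4.83 times higher than with the in vitro peaks shifted by 50 kb, and 20.1 times higher with every peak trimmed to its central 200 bp. Seen from the other side, 6093 of the 57512 in vitro peaks (10.6%, 10.3 to 10.8) lay on a control region and 20.7% on a region of any in vivo list. The share on a control region went up with the in vitro score, from 5.93% (5.33 to 6.57) in the lowest decile to 22.7% (21.6 to 23.8) in the highest. Placement at random gave 1.75% and 2.30% in these deciles. The in vitro list has no replicate.

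The highest in vitro scores were saturated, with 57 peaks at 3100 or above, and ties were ordered by position. The highest, 3142.8, was at chromosome 17, 57808979 to 57814730. The next 4 were at chromosome 1, 90121879 to 90129069 and 90148615 to 90166923, and at chromosome 10, 17125944 to 17127273 and 94190209 to 94191866. The 2 on chromosome 1 and the second on chromosome 10 lay on control regions, and the others lay on regions of other classes. The 2 peaks on chromosome 1 spanned 7191 and 18309 bp, and the highest peak 5752 bp. The median width in the in vitro list was 846 bp. No filter for artefact regions was applied here, and whether such wide peaks are PU.1 sites was not tested.

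The fourth comparison set the in vitro list against the fate of sites under the hairpin. An in vitro peak lay in 39.5% of kept regions (exact 95% interval 38.4 to 40.5), 25.7% of partial ones (24.7 to 26.8), 13.3% of lost ones (12.5 to 14.2) and 31.0% of gained ones (25.5 to 36.9). Random placement gave between 4.34% and 5.67% in the same classes. Absence from both shPU.1 lists did not by itself go with a low share. An in vitro peak lay in 26.9% of the 9410 regions seen only in control replicate 2. The share was 6.94% of the 5345 regions seen only in control replicate 1. The low share of lost regions therefore cannot be ascribed to the hairpin alone. Of the control regions with an in vitro peak, 57.1% were kept and 14.0% lost; of those without, 33.4% were kept and 34.8% lost. Within every decile of rank the kept share was higher with an in vitro peak, for example 13.4% against 7.02% in the lowest, 50.3% against 31.9% in the sixth and 93.5% against 80.2% in the highest. The odds ratio of being kept rather than lost, within rank deciles, was 3.96 (95% interval 3.54 to 4.40). It leaves out the 6713 partial regions and was 2.32 (2.17 to 2.50) with these counted as lost.

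The size of that odds ratio depended on which control library defined the regions, and the control libraries differed in peak width. It was 1.70 (1.56 to 1.83) without control replicate 1, 6.65 (6.08 to 7.30) without control replicate 2, 2.95 without shPU.1 replicate 1 and 2.04 without shPU.1 replicate 2. Within replicate numbers, all regions of the control library were taken, including those absent from the other control library. The odds ratio of finding such a region in the shPU.1 library was 2.92 (2.74 to 3.12) for number 1 and 1.48 (1.39 to 1.56) for number 2, within deciles of the control score. The 2 control libraries themselves gave opposite values: a region of control replicate 1 was found in control replicate 2 more often if it held an in vitro peak (odds ratio 3.71, 3.37 to 4.11), and a region of control replicate 2 was found in control replicate 1 less often (0.510, 0.479 to 0.540).

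**Figure D2:**
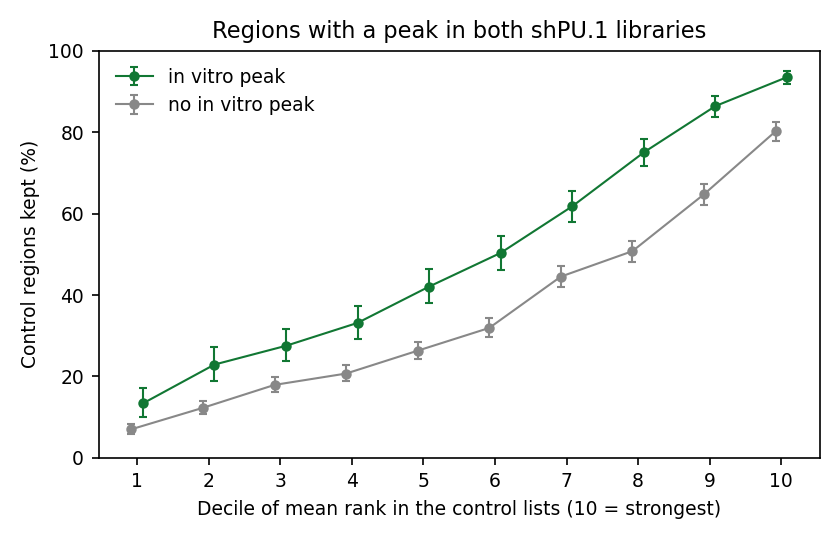
Share of control regions with a peak in both shPU.1 libraries (percent, y axis) by decile of mean rank in the control lists (x axis, 10 is the strongest), for regions with an in vitro peak (green) and without (grey); bars are exact 95% intervals over regions. The kept share goes from 13.4% to 93.5% with an in vitro peak and from 7.02% to 80.2% without.

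**Figure D3:**
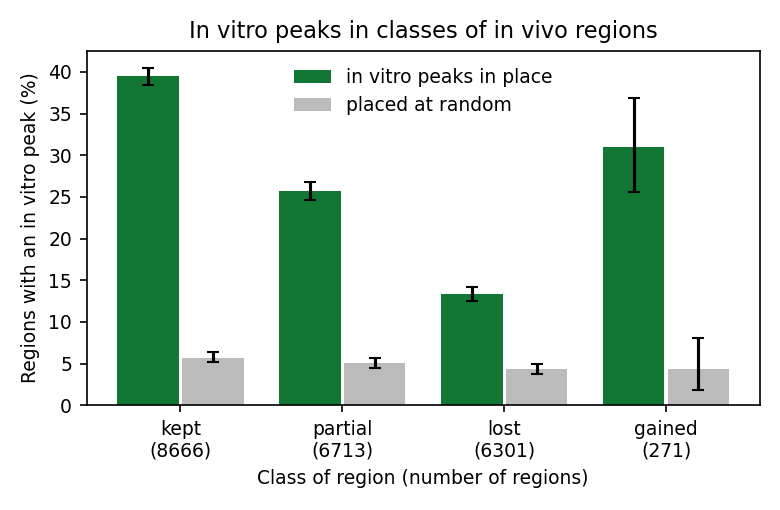
Percent of regions holding an in vitro peak in each class of in vivo region (green bars with exact 95% intervals) and the mean of 100 random placements of the in vitro peaks (grey bars, with their range). Kept regions reach 39.5%, lost regions 13.3% and random placement at most 5.67% on average. Regions seen only in control replicate 1 or only in control replicate 2, not drawn, reach 6.94% and 26.9%.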

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

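The limit on every value is that depth is unknown and each group has 2 libraries. All alternatives kept the side of no difference for the ratio of peak numbers (7 values), the area under the curve (8), the in vitro overlap (10) and the odds ratio (14). The last 3 still moved outside their intervals in 6, 7 and 7 cases. The ratio of lost to gained regions kept its side in 7 of 8 cases and the Jaccard difference in 6 of 8. The kept and the lost share each moved outside the counting interval in 8 of 9 cases. The shares of control regions kept and lost were 32.3% and 31.3% at a score of at least 100, 34.8% and 32.4% with peaks trimmed to the central 200 bp, and 58.7% and 19.2% with equal list lengths. The log2 ratio of lost to gained regions was 5.08, 4.26 and 0.92 in the same order. Leaving out 1 library gave kept shares of 26.9% to 67.5%, lost shares of 32.5% to 56.9% and log2 ratios of -0.11 to 5.27. By construction, fewer libraries then have to show a peak. The ratio reversed to -0.11 without shPU.1 replicate 1. The Jaccard difference between groups ran from -0.036 to 0.229. It reversed to -0.036 without control replicate 1 and to -0.019 without control replicate 2. Only the shPU.1 pair then remained within groups. Over the regions of all 4 lists this pair had a similarity of 0.316. That was below shPU.1 replicate 2 with control replicate 1 (0.385) and control replicate 2 (0.431). It was above shPU.1 replicate 1 with them (0.295 and 0.273). The odds ratio for in vitro peaks stayed above 1 throughout, from 1.70 without control replicate 1 to 6.65 without control replicate 2. It was 5.82 at a score of at least 100, 5.31 with equal list lengths and 2.32 with partial regions counted as lost.

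Taking the replicate number as a block gave a log2 ratio of peak numbers of -0.70. The mean share of a control library's peaks found in the shPU.1 library of the same number was 43.6%, with 56.4% missing. The labels do not say that a number marks a shared mouse or day. Region by region, differences between the numbers had a correlation between the groups of 0.105 over ranks of 8666 regions and 0.032 over presence. The lists as a whole did share features by number: both number 2 lists had wider peaks and more of them than the number 1 list of their group, and 3468 regions were in both number 2 lists only, against 153 in both number 1 lists only. Leaving out chromosomes X, Y and M kept every value on the same side, and 50 strata gave an odds ratio of 3.94, and in vitro overlap with control peaks alone 3.87. These settings and the odds ratios between single lists were chosen after seeing the data. The alternatives for promoters, the motif and gene lists were not run.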

Other observations

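Peaks were sparse on chromosome X. It held 2.74 and 4.18 peaks per Mb in the control lists, 1.24 and 2.41 in the shPU.1 lists and 6.72 in the in vitro list. The ratios to the peaks per autosomal Mb were 0.229, 0.287, 0.207, 0.218 and 0.295 in the same order. Of the 334 control regions on chromosome X, 31.7% were kept and 37.7% lost, against 40.1% and 28.9% on autosomes. X regions also ranked lower (median percentile 52.8 against 61.6), and within rank deciles the odds ratio of being kept was 0.966 (95% interval 0.768 to 1.19). About as many control regions had another control region within 10 kb (9870) as did not (11810). The shares kept were 41.7% and 38.5%.

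Regions found in a single list differed in how often they held an in vitro peak. The share was 26.9% of the 9410 regions seen only in control replicate 2, against 6.94% of 5345 in control replicate 1, 6.00% of 3216 in shPU.1 replicate 1 and 12.0% of 7321 in shPU.1 replicate 2. Median widths of these regions were 731, 353, 408 and 763 bp in the same order. Random placement of the in vitro peaks gave 3.76%, 2.88%, 2.96% and 3.84%, so the shares were 7.17, 2.41, 2.03 and 3.13 times higher.

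The tests below were stated before their results were computed, but after the odds ratio of 3.96 and the peak counts had been seen. The test on control peaks alone was added after the other width test had been seen. The higher kept share of control regions with an in vitro peak had an odds ratio of 3.96, but 2.32 with partial regions counted as lost, 1.70 without control replicate 1, 6.65 without control replicate 2, 2.95 without shPU.1 replicate 1 and 2.04 without shPU.1 replicate 2. Moving the in vitro peaks by 50 kb to either side left an odds ratio of 1.30 (1.12 to 1.48). This argues against background shared over 50 kb as the whole cause. Background confined to the site itself was not tested. Strata of rank and region width gave 4.32 (3.88 to 4.82), which decides nothing, because shPU.1 peaks widen the kept regions. With width and in vitro overlap taken from the control peaks alone it was 3.80 (3.41 to 4.23), which argues against the width of the control peaks as the whole cause. Repeatability of detection stays open: the log odds ratio of being found in the other control library was 0.397 (0.316 to 0.473) of that for the shPU.1 libraries in the mean, but 1.0 for regions of control replicate 1 and -1.93 for those of control replicate 2. The bound set on the mean was therefore not a fair test, because the control lists disagree in sign. A candidate explanation was that PU.1 stays longest where the DNA itself attracts it in proportion to the in vitro score. Within rank deciles, regions with in vitro scores above the median had an odds ratio of 0.957 (0.796 to 1.16) against the rest. No effect of the score beyond rank was therefore seen. Without regard to rank, 60.4% of the regions above the median were kept and 13.2% lost, against 53.8% and 14.8% of the rest. Their median rank percentile was also higher (71.6 against 66.4). Higher ranks went with keeping, so holding rank fixed could remove such an effect. The test therefore does not decide on the explanation as a whole. Base composition was not tested.

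Fewer control regions were found in the shPU.1 libraries, and a lower depth of those libraries could produce this. The test assumed that, if depth alone acted, finding a region would depend on its rank in the same way for any second library. This assumption was not checked, and the odds ratio could also change with the depth of the second library. Over all regions of each control list, the mean log odds ratio for in vitro peaks was larger by 0.483 (0.406 to 0.566) for the shPU.1 libraries than for the other control library. As above, the control lists also gave opposite signs. For both reasons, depth and knockdown cannot be told apart for these regions from the peak lists. Different calling settings for the replicates stay open as well and were not tested.

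The low peak density on chromosome X may reflect 1 copy of it in male cells, though the labels used here do not give the sex of the mice. Peaks on chromosome Y were present in every list (23 to 43). If scores scale with copy number, X should hold as many peaks per Mb as autosomes keep when their scores are divided by 2. The highest ratio of the 5 lists was 0.641 (0.557 to 0.735, in shPU.1 replicate 1), so a single copy would not account for the whole difference under that assumption. The assumption was not checked, and a score based on a p-value need not scale with copy number. The test therefore does not decide whether a single copy accounts for the difference. A lower content of PU.1 sites on chromosome X remains open and was not tested.

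A further hypothesis was that control regions lying in clusters keep PU.1 more often. Within rank deciles, regions with another control region within 10 kb had an odds ratio of being kept of 0.946 (0.866 to 1.03). No effect of a neighbour beyond rank was therefore seen. Without regard to rank, 41.7% of regions with a neighbour were kept and 29.5% lost, against 38.5% and 28.7% of the rest. Their median rank percentile was also higher (62.9 against 60.3). Holding rank fixed could remove an effect of clusters, so the test does not decide on the hypothesis as a whole.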
